A study of Mus musculus with 9 samples.

How the data were processed

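RNA of laser-captured cells from E8.5 embryos, E13.5 dorsal root ganglia and P90 adrenal medullae of mice was measured on 9 Affymetrix mouse arrays, 3 per stage. Per the labels' protocols, RNA was extracted with a PicoPure kit and biotin-labelled cRNA was made from 400 ng of total RNA. The labels name the 3 samples of each stage biological replicates, without the number of animals per capture.

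The deposited table holds 1 intensity per probe set and array, on a linear scale with a floor of 1, as its values show. The submitters' notes name MAS5, GCOS, RMA and GCRMA without a role or version. Which of them made the table, and how it was scaled, is not stated. Of 405909 cells, 8048 (1.98%) were empty, for no stated reason. Of 45101 probe sets, 64 were controls, 34945 had 1 gene symbol, 932 had several and 9160 had none in the annotation used; only those with 1 symbol were analysed. Entrez identifiers of 34741 probe sets matched the gene table, which changed 0 symbols.

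Signals were used as log2(signal + 16) without further scaling between arrays, so changes of dim genes are understated. A probe set was kept where its log2 value passed the 40th percentile of all values, a signal of 26.1, on at least 3 of 9 arrays. Because of unforeseen empty cells, at least 2 values per stage were also required. A total of 24012 probe sets passed, and the brightest per gene represented 13747 of 18193 genes. Stages were compared in 1 limma fit of all 9 arrays with 6 residual degrees of freedom (lmFit, eBayes with a variance trend, two-sided), with Benjamini-Hochberg adjustment over genes and a call at an adjusted p under 0.05. A limma F-test asked for a difference between any stages. Gene lists were tested with camera at a preset correlation of 0.01, on the 12755 tested genes with no empty cell and for lists of at least 5 such genes, with adjustment over 37 sets per comparison. The adrenal cortex and sex chromosome lists had too few such genes and got no set test, and the union of the repair lists is 1 of the 37 sets. Camera was repeated with an estimated correlation, and fry was run too. Over the other 36, camera called 20, 13 and 22 at E13.5 against E8.5, P90 against E13.5 and P90 against E8.5, and with an estimated correlation 0, 1 and 1, the 1 being class I antigen presentation.

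Except for stated additions and rules on empty cells, the tests, 38 gene lists, naming rule and settings were fixed before the data were seen. The 9 DNA repair lists were base excision, nucleotide excision, mismatch, homologous recombination, end joining, Fanconi anaemia, translesion synthesis, direct reversal and nucleotide pool, and damage signalling; they name 166 genes, of which 153 were annotated and 143 tested. The others were p53 targets, DNA replication, mitosis, cell cycle inhibitors, embryonic growth programme, imprinted growth genes, neural crest specification, neural tube progenitor, sensory neuron, pan-neuronal, Schwann and satellite glia, chromaffin and catecholamine, secretory granule and neuropeptide, class I antigen presentation, Hox genes, immediate early and dissociation stress, oxidative phosphorylation, glycolysis, antioxidant defence, cholesterol synthesis, cytosolic ribosomal proteins and sex chromosome transcripts. Markers of other cell types made up the rest: adrenal cortex, red cells, endothelium, mesenchyme, muscle and somite, surface and gut epithelium, and macrophage and immune. Named genes were, per comparison, the 5 largest rises and 5 largest falls among called genes with no empty value whose arrays separate by stage (Riken and predicted genes passed over), the 6 largest falls and 4 largest rises among called repair genes, and the 1 or 2 most changed called members of every other list in the direction of most of its calls. A set of 26 check genes came on top, of which 4 were not analysed here. Genes outside this rule are said to have been chosen after their values were seen.

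Alternatives were quantile normalization, pseudocounts of 1 and 64, other filters, other variance models, fits of only the arrays compared, other choices of probe set, a replicate block, array weights, a change of at least 2-fold, and leaving out each array. Limma's planned estimate of array weights did not converge; a gene-by-gene estimate was added after the planned counts had been seen. Also added after seeing the data were the Actb difference as a covariate, with and without quantile normalization, leaving out the array of each stage with the largest Actb difference, and keeping only genes with no empty cell. Shared E8.5 controls were simulated with 100 draws of unchanged groups.

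On simulated data with 200 changed genes of 13747, the fit recovered 5%, 3% and 7% of genes changed by a log2 size of 1 at E13.5 against E8.5, P90 against E13.5 and P90 against E8.5, and 59%, 59% and 67% at a size of 2, with 3, 5 and 10 false calls. Of 27 unshifted sets, camera called 1, 0 and 0. Genes were simulated independently, so this check does not cover correlation between genes in the real data. Of 200 random lists, 8.5% fell under the 5th percentile and 4% over the 95th of matched lists. Analyses used R 4.3.3 and limma 3.58.1, and plots Python 3.11.15 with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.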

Results

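Gene expression was measured on 9 mouse arrays, 1 per sample, of cells laser-captured by the submitters as neural crest or its derivatives. Neural crest cells leave the closing neural tube and give rise to sensory ganglia, glia and the adrenal medulla. E8.5 embryos at neural tube closure, E13.5 dorsal root ganglia and adult (P90, 3 months) adrenal medullae gave 3 arrays each. Median array signals were 38.3 to 48.2 and 75th percentiles 152 to 214. Means were 267 to 279 (E8.5), 178 to 327 (E13.5) and 173 to 304 (P90). Few arrays limit precision throughout. Over probe sets, log2 signals correlated at r = 0.834 to 0.985 between arrays of a stage and 0.697 to 0.855 between stages. The log2 difference between the 3' and 5' control probe sets of Actb, a sign of RNA integrity, averaged 3.09 ± 1.51 at E8.5, 3.57 ± 3.13 at E13.5 and 2.99 ± 1.44 at P90 (SD, n = 3). It was largest, at 7.0, on E13.5 replicate 2. Stage and tissue change together in this design, so each comparison is between both at once. Signals are mean ± SD, and changes are log2 changes of signal plus 16 (± SE), tested with limma, from 3 arrays per stage unless 1 value was empty. For a named gene past the test, all 3 arrays of one stage lay beyond all 3 of the other, except for genes with an empty value and where stated.

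The first comparison asked how the E13.5 dorsal root ganglion differs from E8.5 neural crest, with DNA repair genes as the stated object of the study. Of 143 repair genes tested, 1 rose, 40 fell and 102 were not called (adjusted over the list alone, 3 rose and 48 fell). Exo1, an exonuclease of mismatch repair and recombination, went from a signal of 985 ± 176 to 75.6 ± 13.8 (n = 3 each; log2 -3.45 ± 0.29, adjusted p = 6.17e-05). Gen1, a resolvase of Holliday junctions, went from 286 ± 29.7 to 11.8 ± 6.79 (n = 3 each; log2 -3.47 ± 0.26, adjusted p = 3e-05). Prtg, a neural receptor, fell from 3530.2 ± 438 to 12.3 ± 2.84 (n = 3 each; log2 -6.97 ± 0.29, adjusted p = 5.92e-07). Isl1, a LIM homeodomain factor of sensory neurons, went from 58.9 ± 78.4 to 4513 ± 1179 (n = 3 each; log2 6.39 ± 0.99, adjusted p = 0.00121).

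The next largest falls among repair genes were in Rad54l, Tipin, Brca1 and Msh6. Rad54l, a DNA translocase of homologous recombination, fell from 788 ± 338 to 72.9 ± 5.72 (n = 3 each; log2 -3.1 ± 0.32, adjusted p = 0.000116). Tipin, which protects stalled replication forks, fell from 926 ± 234 to 118 ± 96.2 (n = 3 each; log2 -3.07 ± 0.5, adjusted p = 0.0016). Brca1, central to homologous recombination, had 1 empty value at E8.5 (log2 -3.05 ± 0.34, adjusted p = 0.000288), and 1 of its 2 probe sets moved in this direction. Msh6, a mismatch recognition protein, fell from 1047 ± 431 to 141 ± 114 (n = 3 each; log2 -2.96 ± 0.56, adjusted p = 0.00387). The only repair gene that rose was Paxx, an end joining factor, from 23.1 ± 7.78 to 85.7 ± 3.71 (n = 3 each; log2 1.4 ± 0.24, adjusted p = 0.00235). Not called were the check genes Atm (log2 -0.56, adjusted p = 0.499), Parp1 (log2 -0.61, adjusted p = 0.374), Mgmt (log2 0.35, adjusted p = 0.418), Lig4 (log2 -0.34, adjusted p = 0.693), Ercc1 (log2 -0.07, adjusted p = 0.941) and Xpa (log2 0.14, adjusted p = 0.837). The median repair gene changed by -0.52, against 0.02 for all genes tested. Camera ranked repair genes below other genes only at its preset correlation (camera adjusted p = 2.06e-09 and 0.175 with estimated correlation), and fry, which asks whether a set's genes move one way, gave adjusted p = 0.00394. Without E8.5 replicate 2 or without E8.5 replicate 3, 27 repair genes passed the test in place of 41. Xrcc1, a scaffold of base excision repair, fell (log2 -1.39 ± 0.38, adjusted p = 0.0279), but its call was lost without any E8.5 array or E13.5 replicate 2 or 3 (adjusted p from 0.0571 to 0.101).

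Pathway genes not named above were chosen after their values were seen. Of 24 homologous recombination genes, 12 fell and 12 were not called (over the list alone, 12 fell), among them Rad51ap1 (-2.81), Palb2 (-2.53) and Brca2 (-2.22). For homologous recombination, camera gave adjusted p = 4.86e-08 and 0.101 with estimated correlation. Of 19 damage signalling genes, 9 fell and 10 were not called (over the list alone, 11 fell), with the checkpoint kinases Chek1 (-2.48) and Chek2 (-2.19). For damage signalling, camera gave adjusted p = 4.59e-08 and 0.129 with estimated correlation. In the Fanconi anaemia pathway, 6 fell and 12 were not called (over the list alone, 8 fell) out of 18, with Cenps (-2.77), Usp1 (-2.54) and Ube2t (-2.4) in front. For Fanconi anaemia, camera gave adjusted p = 0.000999 and 0.143 with estimated correlation. For mismatch repair, 3 fell and 4 were not called (over the list alone, 3 fell) out of 7, with Exo1 (-3.45) and Msh6 (-2.96) in front. For mismatch repair, camera gave adjusted p = 0.00614 and 0.101 with estimated correlation. Of 19 base excision repair genes, 3 fell and 16 were not called (over the list alone, 7 fell), including Lig1 (-2.69). For base excision, camera gave adjusted p = 0.0231 and 0.368 with estimated correlation. In nucleotide excision repair, 3 fell and 23 were not called (over the list alone, 1 fell) out of 26, with Rpa2 (-2.78) in front (camera adjusted p = 0.0607). Of 14 translesion synthesis genes, 3 fell and 11 were not called (over the list alone, 3 fell), among them Rad18 (-2.09), with camera adjusted p = 0.292 for the list. Among 10 end joining genes, 1 rose, 1 fell and 8 were not called (over the list alone, 1 rose and 1 fell), Paxx being the riser (camera adjusted p = 0.589). Of 6 genes of direct reversal and the nucleotide pool, limma called 0 (1 higher and 2 lower at unadjusted p under 0.05; 0 over the list alone; camera adjusted p = 0.63). Parp2, Pms2, Rad23b, Rpa1, Pcna, Rev1 and Xrcc5 fell too, but each lost its call without any E8.5 array, and all but Parp2 also without some of E13.5 replicates 1, 2 and 3 and P90 replicates 2 and 3 (adjusted p from 0.0532 to 0.153). Neither these nor Lig1 or Xrcc1 were called without the array of each stage with the largest Actb difference (adjusted p from 0.0646 to 0.234, range over alternatives 3.14e-08 to 0.247), and 5 of the 7 were not with no filter.

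**Figure D1:**
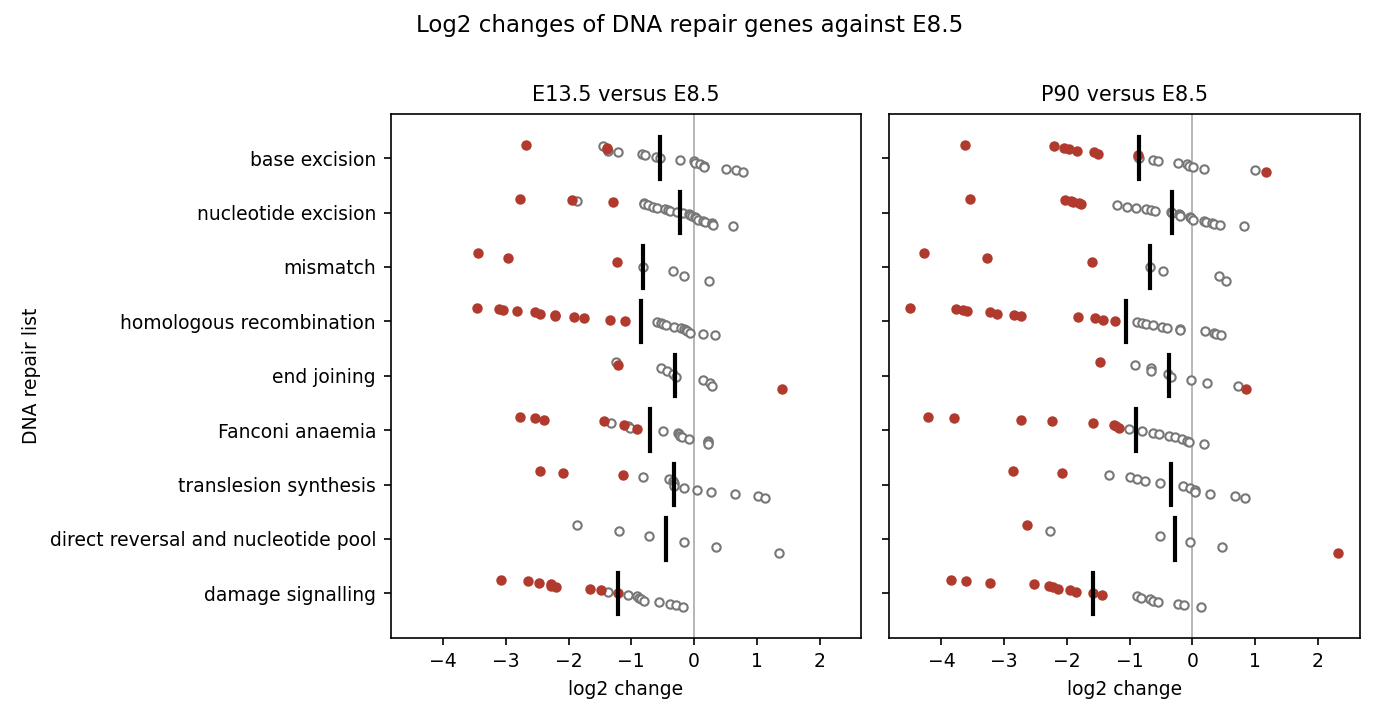
Log2 change of each tested gene in the 9 DNA repair lists, at E13.5 against E8.5 and at P90 against E8.5, where filled red dots have an adjusted p under 0.05, open grey dots do not, and black bars are list medians. Homologous recombination (medians -0.85 and -1.05) and damage signalling (medians -1.21 and -1.59) lie furthest below 0.

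**Figure D2:**
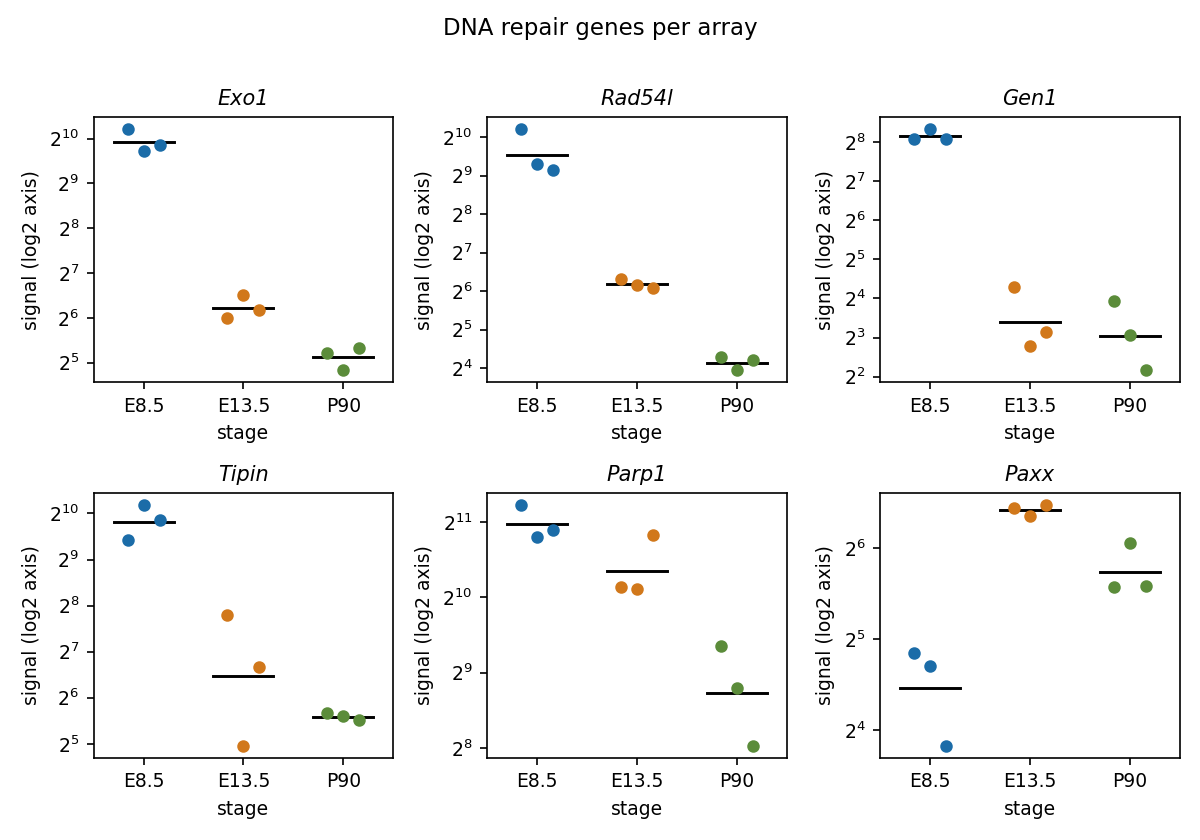
Signal of 6 DNA repair genes on the 9 arrays (log2 axis, a dot per array, a black bar at the geometric mean of each stage). Exo1, Rad54l and Gen1 sit below all E8.5 arrays at both later stages, and Paxx sits above them at E13.5.

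Most replication and mitosis genes fell. Of 35 DNA replication genes, 29 fell and 6 were not called (over the list alone, 32 fell), led by Cdc6, a loader of replicative helicase with 1 empty value at E8.5 (log2 -3.92 ± 0.35, adjusted p = 8.35e-05), and Rfc5, a clamp loader subunit (log2 -3.63 ± 0.59, adjusted p = 0.00163). For DNA replication, camera gave adjusted p = 7.37e-19 and 0.101 with estimated correlation. For mitosis, 29 fell and 5 were not called (over the list alone, 32 fell) out of 34, led by the spindle checkpoint kinase Bub1 (log2 -3.69 ± 0.39, adjusted p = 0.00014) and by Plk1 (log2 -3.23 ± 0.33, adjusted p = 0.000111). For mitosis, camera gave adjusted p = 1.7e-22 and 0.101 with estimated correlation. Mki67, a marker of cycling cells, went from 3639 ± 422 to 859.6 ± 289.5 (n = 3 each; log2 -2.12 ± 0.38, adjusted p = 0.00263). Among 12 cell cycle inhibitors, 1 fell and 11 were not called (over the list alone, 2 rose and 1 fell), and the faller, Gas1 (log2 -2.46 ± 0.65, adjusted p = 0.0231), lost its call without E8.5 replicate 2 or 3 or E13.5 replicate 2 (adjusted p from 0.0614 to 0.104); the set gave camera adjusted p = 0.125. Of 16 p53 targets, 2 rose and 14 were not called (over the list alone, 4 rose; camera adjusted p = 0.432). Sesn1 (log2 1.67 ± 0.38, adjusted p = 0.0101) was not called once probe sets ending in _x_at and _s_at were left out (log2 change 0.77, adjusted p = 0.543, range over all alternatives 8.63e-08 to 0.543). Plk2 (log2 2.51 ± 0.73, adjusted p = 0.0365) was not called without any E8.5 array, E13.5 replicate 1 or 3 or P90 replicate 2 or 3 (adjusted p from 0.05 to 0.14). Of 11 embryonic growth programme genes, 8 fell and 3 were not called (over the list alone, 9 fell), such as the pluripotency factor Sall4 (log2 -4.32 ± 0.26, adjusted p = 1e-05), Igf2bp1 (log2 -3.42 ± 0.41, adjusted p = 0.000278) and Lin28a, a repressor of let-7 processing (log2 -2.61 ± 0.23, adjusted p = 7.29e-05). For growth genes, camera gave adjusted p = 4.59e-08 and 0.101 with estimated correlation.

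Some early neural and crest factors fell and most neuronal genes rose. For neural crest specification, 7 fell and 14 were not called (over the list alone, 7 fell) out of 21, led by Pax3 (log2 -3.28 ± 0.45, adjusted p = 0.000642) and Msx1 (log2 -2.42 ± 0.38, adjusted p = 0.00143). For crest genes, camera gave adjusted p = 0.00614 and 0.175 with estimated correlation. The crest factor Foxd3 fell (log2 -1.54 ± 0.46, adjusted p = 0.0404), a call lost without any E8.5 array, any E13.5 array or P90 replicate 3 (adjusted p from 0.0502 to 0.163), while Sox10 was not called (log2 0.71, adjusted p = 0.197). Of 15 neural tube progenitor genes, 6 fell and 9 were not called (over the list alone, 6 fell), led by Wnt1, a signal of the dorsal neural tube (log2 -4.54 ± 0.25, adjusted p = 4.86e-06), and Pax6 (log2 -3.85 ± 0.24, adjusted p = 1e-05). For neural tube genes, camera gave adjusted p = 0.000102 and 0.101 with estimated correlation. Of 18 sensory neuron genes, 11 rose, 1 fell and 6 were not called (over the list alone, 11 rose and 1 fell), with Isl1 and Runx1, which had 1 empty value at E13.5 (log2 6.0 ± 0.44, adjusted p = 4.57e-05), rising most. For sensory neuron genes, camera gave adjusted p = 0.000351 and 0.101 with estimated correlation. The faller was Neurog2 (-4.13), a neurogenic factor of sensory precursors named after its value was seen. Of 22 pan-neuronal genes, 16 rose and 6 were not called (over the list alone, 18 rose), such as the microtubule protein Mapt, from 91.1 ± 6.61 to 3834 ± 1254 (n = 3 each; log2 5.12 ± 0.5, adjusted p = 8.57e-05). For pan-neuronal genes, camera gave adjusted p = 2.33e-10 and 0.101 with estimated correlation. In these neuronal lists 10 sensory neuron and 10 pan-neuronal genes had a probe set that was empty on all 3 E13.5 arrays. One is the neurofilament gene Prph, whose brighter probe set was empty there and whose other probe set was not called (log2 0.56, adjusted p = 0.189).

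Glial and neuroendocrine genes rose in part. For Schwann and satellite glia, 5 rose and 8 were not called (over the list alone, 6 rose) out of 13, led by the calcium-binding protein S100b (log2 3.25 ± 0.4, adjusted p = 0.000319) and Mbp, a myelin protein (log2 3.88 ± 0.65, adjusted p = 0.0019). For glia, camera gave adjusted p = 0.00208 and 0.157 with estimated correlation. Mbp was not called when probe sets ending in _x_at and _s_at were left out (log2 change 0.41, adjusted p = 0.52, range 5.13e-08 to 0.52). Of 17 secretory granule and neuropeptide genes, 9 rose and 8 were not called (over the list alone, 9 rose), such as the neuropeptide Gal (log2 5.16 ± 0.6, adjusted p = 0.000251) and the granule protein Chga (log2 3.64 ± 0.44, adjusted p = 0.000294). For granule genes, camera gave adjusted p = 2.22e-06 and 0.129 with estimated correlation. Of 16 chromaffin and catecholamine genes, 2 rose and 14 were not called (over the list alone, 4 rose and 1 fell; camera adjusted p = 0.517). Th, the first enzyme of catecholamine synthesis, rose (log2 2.55 ± 0.39, adjusted p = 0.00156), while Dbh (log2 0.4, adjusted p = 0.735) and Pnmt (log2 0.65, adjusted p = 0.511), later enzymes of that pathway, did not pass. Among genes with no empty value, the rest with the largest rise were Mmd2 (log2 6.57 ± 0.51, adjusted p = 3.65e-05), the Cdk5 activator Cdk5r2 (log2 6.51 ± 0.96, adjusted p = 0.000884), Rgs4 (log2 6.48 ± 0.45, adjusted p = 2.28e-05) and the gliogenic factor Nfia (log2 5.93 ± 0.61, adjusted p = 0.000112). Of these genes, the rest with the largest fall were hexokinase Hk2 (log2 -4.66 ± 0.58, adjusted p = 0.000319), Tfap2c (log2 -4.43 ± 0.28, adjusted p = 1e-05) and the glycine cleavage enzyme Gldc (log2 -4.38 ± 0.63, adjusted p = 0.000749). Without probe sets ending in _x_at and _s_at, Mmd2 (log2 change 2.05, adjusted p = 0.0921, range 7.73e-12 to 0.0921) and Tfap2c (log2 change -0.23, adjusted p = 0.706, range 7.73e-12 to 0.706) were not called.

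Of 13 epithelial genes, 5 fell and 8 were not called (over the list alone, 6 fell), led by the keratins Krt18 (log2 -4.3 ± 0.5, adjusted p = 0.000254) and Krt8 (log2 -3.76 ± 0.41, adjusted p = 0.000172). For epithelium, camera gave adjusted p = 0.00227 and 0.175 with estimated correlation. Of 18 mesenchyme genes, 6 rose, 1 fell and 11 were not called (over the list alone, 6 rose and 1 fell), led by the proteoglycan Dcn (log2 5.31 ± 0.75, adjusted p = 0.000704) and the collagen Col6a2 (log2 2.85 ± 0.34, adjusted p = 0.000285), with Fbln1 (-2.06), named after its value was seen, as the faller. For mesenchyme, camera gave adjusted p = 0.0526. Of 17 endothelial genes, 4 rose and 13 were not called (over the list alone, 6 rose), for example Robo4 (log2 1.86 ± 0.31, adjusted p = 0.00179). For endothelium, camera gave adjusted p = 0.00361 and 0.415 with estimated correlation. Of 17 macrophage genes, 2 rose and 15 were not called (0 over the list alone, where limma gave 6 higher and 0 lower at unadjusted p under 0.05); C1qc (adjusted p = 0.0416) lost its call without any E8.5 array, E13.5 replicate 1 or 3 or P90 replicate 2 (adjusted p from 0.057 to 0.17), and H2-Ab1 (adjusted p = 0.0423) without any E8.5 array, any E13.5 array or P90 replicate 3 (adjusted p from 0.0509 to 0.182). H2-Ab1 turned to log2 change -0.5, adjusted p = 0.211, once probe sets ending in _x_at and _s_at were left out (range 1.45e-05 to 0.427). For the macrophage list, camera gave adjusted p = 0.0126 and 0.227 with estimated correlation. Among 10 red cell genes, 2 rose, 1 fell and 7 were not called (over the list alone, 2 rose and 2 fell); the median was 0.15 and the mean 0.14, while the test pointed down. For red cells, camera gave adjusted p = 0.65. The red cell risers were Alas2, whose call was lost without E13.5 replicate 2 (adjusted p = 0.0544), and Slc4a1, whose stages overlapped, lost without E8.5 replicate 1 or 2 or E13.5 replicate 1 or 2 (adjusted p from 0.0778 to 0.113), and the faller was the embryonic globin Hbb-bh1 (-3.31), named after its value was seen, lost without E8.5 replicate 3 (adjusted p = 0.0515). Of 12 muscle and somite genes, 2 rose, 1 fell and 9 were not called (over the list alone, 2 rose and 1 fell), with median 0.09, mean -0.08 and a test that pointed down (camera adjusted p = 0.955). The muscle risers lost their calls, Actc1 without any E8.5 array, E13.5 replicate 3 or P90 replicate 2 or 3 (adjusted p from 0.0535 to 0.28) and Tnnc1 without E8.5 replicate 2 or 3 or E13.5 replicate 1 or 3 (adjusted p from 0.0591 to 0.0995). Of 7 adrenal cortex genes, 1 rose and 6 were not called (over the list alone, 1 rose), the riser being the steroidogenic factor Nr5a1 (log2 2.0 ± 0.32, adjusted p = 0.00186), with a list median of 0.18. Of 14 genes of class I antigen presentation, 1 fell and 13 were not called (0 over the list alone, where limma gave 0 higher and 2 lower at unadjusted p under 0.05), the median being 0.05 and the mean -0.2 (camera adjusted p = 0.586, pointing down). The faller, H2-K1 (log2 -2.29 ± 0.65, adjusted p = 0.0326), lost its call without any E8.5 array or E13.5 replicate 2 or 3 (adjusted p from 0.0743 to 0.121).

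Over all genes, 2267 of 13747 passed the test, 1275 of them higher and 992 lower at E13.5, and 2189 changed at least 2-fold. In 4567 of the 13063 genes with no empty value, called or not, the stages did not overlap, 35.0% against 10% by chance. Called genes numbered 1355 without E8.5 replicate 2, 1510 without E8.5 replicate 3 and 1510 without E13.5 replicate 3, and 1674 were higher and 788 lower without E13.5 replicate 2.

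The second comparison set the P90 adrenal medulla against the E13.5 dorsal root ganglion. Pnmt, which makes adrenaline from noradrenaline, went from a signal of 40.6 ± 8 to 2557 ± 1682 (n = 3 each; log2 5.16 ± 0.56, adjusted p = 0.000242). Sox11, a factor of immature neurons, fell (log2 -5.64 ± 0.42, adjusted p = 4.59e-05), as did Zic1, a factor of neural and crest precursors (log2 -5.6 ± 0.42, adjusted p = 4.59e-05). Tap2, a peptide transporter of class I antigen presentation, rose from 10.5 ± 1.62 to 222 ± 45.2 (n = 3 each; log2 3.15 ± 0.22, adjusted p = 4.59e-05). Of the 143 repair genes, 5 fell and 138 were not called (over the list alone, 1 fell).

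The 5 repair genes that fell were Ube2t, the ubiquitin-conjugating enzyme of the Fanconi anaemia pathway (log2 -1.41 ± 0.23, adjusted p = 0.00252), Parp1, a sensor of strand breaks (log2 -1.59 ± 0.41, adjusted p = 0.0305), Cenps, a partner of Fancm (log2 -1.45 ± 0.36, adjusted p = 0.0262), Rad54l (log2 -1.39 ± 0.32, adjusted p = 0.0172) and Clspn, a checkpoint adaptor (log2 -0.96 ± 0.27, adjusted p = 0.0425). Ube2t kept its call without any 1 of the 9 arrays. Parp1 (adjusted p from 0.05 to 0.146) and Clspn (adjusted p from 0.0627 to 0.17) lost their calls without E8.5 replicate 2 or 3, E13.5 replicate 1 or 3 or P90 replicate 2 or 3. Cenps lost it without E13.5 replicate 1 or 3 or any P90 array (adjusted p from 0.0535 to 0.0976), and Rad54l without E13.5 replicate 3 or P90 replicate 2 or 3 (adjusted p from 0.057 to 0.0749). With the mean of all probe sets of a gene, Parp1 (range 7.02e-10 to 0.628), Rad54l (range 7.99e-09 to 0.133) and Clspn (range 7.16e-09 to 0.17) were not called, and with a pseudocount of 64 neither were Cenps (range 8.79e-08 to 0.197), Rad54l and Clspn. Without 1 array, the number of called repair genes was 3 (E8.5 replicate 2), 3 (E8.5 replicate 3), 2 (E13.5 replicate 1), 12 (E13.5 replicate 2), 1 (E13.5 replicate 3), 1 (P90 replicate 2) and 1 (P90 replicate 3). With quantile normalization 9 were called, 1 of them higher. The check genes Brca1 (log2 -0.71, adjusted p = 0.215), Msh6 (log2 -0.32, adjusted p = 0.821) and Xrcc1 (log2 -0.17, adjusted p = 0.863) were not called. The median repair gene differed by -0.19, against -0.05 for all genes, and the set did not pass (camera adjusted p = 0.19).

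Among the repair lists, 2 fell and 16 were not called (over the list alone, 2 fell) in the Fanconi anaemia list of 18 (camera adjusted p = 0.284). In base excision, Parp1 made the 1 call among 19 (over the list alone, 1 fell; camera adjusted p = 0.268). Rad54l made that of the 24 homologous recombination genes (over the list alone, 1 fell; camera adjusted p = 0.333). In damage signalling, with 19 genes, 1 fell and 18 were not called (0 over the list alone, where limma gave 1 higher and 2 lower at unadjusted p under 0.05; camera adjusted p = 0.316). Of 26 nucleotide excision genes, limma called 0 (0 higher and 1 lower at unadjusted p under 0.05; 0 over the list alone; camera adjusted p = 0.493). Of 7 mismatch repair genes, limma called 0 (0 higher and 1 lower at unadjusted p under 0.05; 0 over the list alone; camera adjusted p = 0.855). Of 10 end joining genes, limma called 0 (0 higher and 1 lower at unadjusted p under 0.05; 0 over the list alone; camera adjusted p = 0.945). In translesion synthesis, with 14 genes, limma called 0 (0 higher and 2 lower at unadjusted p under 0.05; 0 over the list alone; camera adjusted p = 0.697). In direct reversal and the nucleotide pool, with 6 genes, limma called 0 (0 higher and 0 lower at unadjusted p under 0.05; 0 over the list alone); the median there was 0.12, the mean -0.07, and the test pointed up. For direct reversal, camera gave adjusted p = 0.697.

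Some mitosis and replication genes were lower at P90. For mitosis, 18 fell and 16 were not called (over the list alone, 1 rose and 22 fell) out of 34, led by Mki67, from 859.6 ± 289.5 to 51.8 ± 10.6 (n = 3 each; log2 -3.64 ± 0.38, adjusted p = 0.000164), and the chromosomal passenger protein Birc5 (log2 -3.62 ± 0.48, adjusted p = 0.000695). For mitosis, camera gave adjusted p = 7.98e-14 and 0.209 with estimated correlation. In DNA replication, 8 fell and 27 were not called (over the list alone, 13 fell) out of 35, led by Uhrf1, a cofactor of maintenance DNA methylation (log2 -3.19 ± 0.34, adjusted p = 0.000328). For DNA replication, camera gave adjusted p = 2.45e-05 and 0.357 with estimated correlation. With quantile normalization 13 fell. Of 12 cell cycle inhibitors, 2 rose and 10 were not called (over the list alone, 2 rose and 1 fell); the median was -0.05 (0.08 with quantile normalization), the mean -0.16, and the test pointed up. For cell cycle inhibitors, camera gave adjusted p = 0.493. The risers were Btg2, an antiproliferative p53 target (log2 2.03 ± 0.33, adjusted p = 0.00241), and Cdkn2c (adjusted p = 0.0416), which lost its call without any E8.5 array, E13.5 replicate 2 or 3 or P90 replicate 1 or 2 (adjusted p from 0.0573 to 0.146). Btg2 was also the riser among 16 p53 targets, where 1 rose and 15 were not called (over the list alone, 1 rose; camera adjusted p = 0.456). In the embryonic growth programme, 2 fell and 9 were not called (over the list alone, 3 fell) out of 11, namely Sox2, a factor of neural precursors (log2 -4.28 ± 0.49, adjusted p = 0.000323), and Igf2bp1 (log2 -3.36 ± 0.41, adjusted p = 0.000444). For growth genes, camera gave adjusted p = 0.0113 and 0.53 with estimated correlation.

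Some crest and neuronal genes were lower at P90 and some catecholamine genes higher. For neural crest specification, 6 fell and 15 were not called (over the list alone, 1 rose and 9 fell) out of 21, led by Zic1 and Nr2f1 (log2 -2.93 ± 0.5, adjusted p = 0.00331). For crest genes, camera gave adjusted p = 0.0106 and 0.357 with estimated correlation. Sox10 fell (log2 -2.0 ± 0.34, adjusted p = 0.00332), with 1 of its 2 probe sets in this direction and no call with the mean of all probe sets (log2 change -0.9, adjusted p = 0.0815, range 1.25e-10 to 0.0815), and Foxd3 was not called (log2 -1.23, adjusted p = 0.136). Of 15 neural tube progenitor genes, 1 fell and 14 were not called (over the list alone, 1 fell), that gene being Sox2 (camera adjusted p = 0.328). Of 18 sensory neuron genes, 1 rose, 6 fell and 11 were not called (over the list alone, 1 rose and 9 fell), with falls in Runx1 (log2 -5.0 ± 0.44, adjusted p = 0.000111; 1 empty value at E13.5) and Isl2 (log2 -3.86 ± 0.32, adjusted p = 6.89e-05) and a rise in Th. For sensory neuron genes, camera gave adjusted p = 0.000965 and 0.186 with estimated correlation. Isl1 was not called (log2 -2.75, adjusted p = 0.12), its P90 signals being 88.9, 1876 and 1419.5 on replicates 1, 2 and 3. Of 22 pan-neuronal genes, 7 fell and 15 were not called (over the list alone, 9 fell), such as Dpysl3, with 1 empty value at E13.5 (log2 -4.2 ± 0.57, adjusted p = 0.00123). For pan-neuronal genes, camera gave adjusted p = 0.000306 and 0.472 with estimated correlation. In glia, 3 fell and 10 were not called (over the list alone, 5 fell) out of 13, with S100b (log2 -2.47 ± 0.4, adjusted p = 0.00248) among them (camera adjusted p = 0.185). On P90 replicate 1 pan-neuronal genes lay lower than on P90 replicates 2 and 3 by a median log2 difference of -2.12 and glial genes by -0.69, against 0.25 for all genes.

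Of 16 chromaffin and catecholamine genes, 9 rose and 7 were not called (over the list alone, 10 rose). For catecholamine genes, camera gave adjusted p = 2.03e-06 and 0.151 with estimated correlation. Besides Pnmt they included Dbh, which makes noradrenaline, from 59.7 ± 12.1 to 1516 ± 1050.5 (n = 3 each; log2 3.92 ± 0.61, adjusted p = 0.00192), and Gata2, with 1 empty value at P90 (log2 5.06 ± 0.34, adjusted p = 4.59e-05). Th rose (log2 2.52 ± 0.44, adjusted p = 0.00483; 1 empty value at P90), but lost its call in a fit without the array of each stage with the largest Actb difference (adjusted p = 0.0719, range 6.6e-09 to 0.0719). On P90 replicate 1 the list lay lower than on replicates 2 and 3 by a median of -1.73, as in Pnmt, with signals of 633, 3749 and 3289 on replicates 1, 2 and 3. Of 17 secretory granule and neuropeptide genes, 3 rose, 1 fell and 13 were not called (over the list alone, 3 rose and 1 fell), with Chgb (log2 3.24 ± 0.55, adjusted p = 0.00314) and Chga (log2 2.51 ± 0.44, adjusted p = 0.00386) rising. That list's median was -0.31 (0.02 with quantile normalization), its mean 0.18, and its test pointed up (camera adjusted p = 0.229). Chga lost its call in the fit without those 3 arrays (adjusted p = 0.0561, range 1.56e-11 to 0.0561). Of 7 tested adrenal cortex genes, 2 rose and 5 were not called (over the list alone, 3 rose), with a median of 0.87. The lipoprotein receptor Scarb1 rose (log2 3.97 ± 0.45, adjusted p = 0.000444), with P90 signals of 7157 and 3295 on its 2 arrays with a value, as did Fdx1 (3.58), an electron carrier of steroid synthesis named after its value was seen. Of the 14 annotated genes of that list, 7 had a probe set that was empty on all 3 P90 arrays.

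Genes of class I antigen presentation numbered 14, and 12 rose and 2 were not called (over the list alone, 14 rose), including H2-D1 (log2 3.59 ± 0.68, adjusted p = 0.00579), with 4 of its 6 probe sets in this direction. For class I presentation, camera gave adjusted p = 1.86e-17 and 0.00474 with estimated correlation, which kept the call. Of 17 macrophage genes, 8 rose and 9 were not called (over the list alone, 13 rose), led by the class II genes H2-Aa, with 1 empty value at P90 (log2 5.3 ± 0.35, adjusted p = 4.59e-05), and H2-Eb1 (log2 4.13 ± 0.36, adjusted p = 7.1e-05). For macrophages, camera gave adjusted p = 2.65e-07 and 0.132 with estimated correlation. In mesenchyme, 6 fell and 12 were not called (over the list alone, 6 fell) out of 18, such as fibronectin, Fn1 (log2 -3.22 ± 0.63, adjusted p = 0.00723). For mesenchyme, camera gave adjusted p = 0.00164 and 0.529 with estimated correlation. Of 17 endothelial genes, 1 rose, 1 fell and 15 were not called (over the list alone, 3 rose and 1 fell; camera adjusted p = 0.191). Among 10 red cell genes, 2 fell and 8 were not called (over the list alone, 4 fell), with the embryonic globin Hbb-y, which had 1 empty value at E13.5 (log2 -8.16 ± 0.59, adjusted p = 5.41e-05), and Slc4a1 (log2 -3.32 ± 0.54, adjusted p = 0.00252) as the fallers. For red cells, camera gave adjusted p = 0.185. In muscle, 1 fell and 11 were not called (over the list alone, 1 fell) out of 12, namely Actc1 (log2 -2.28 ± 0.4, adjusted p = 0.00458; 1 empty value at E13.5), with camera adjusted p = 0.618 for the list. In epithelium, 1 fell and 12 were not called (over the list alone, 1 fell) out of 13, with camera adjusted p = 0.816; that gene, Cdh1 (adjusted p = 0.0148), lost its call without E13.5 replicate 3 (adjusted p = 0.152). Among genes with no empty value, the rest with the largest rise, passing over a Riken gene, were Hsd11b1, which regenerates active glucocorticoid (log2 4.34 ± 0.57, adjusted p = 0.000709), and the metallothioneins Mt2 (log2 4.26 ± 0.5, adjusted p = 0.000383) and Mt1 (log2 4.01 ± 0.54, adjusted p = 0.000765). Of these genes, the rest with the largest fall were Id4 (log2 -5.23 ± 0.58, adjusted p = 0.000257), the axonal adhesion molecule Cntn2 (log2 -5.22 ± 0.46, adjusted p = 7.39e-05) and Hoxa9 (log2 -5.11 ± 0.85, adjusted p = 0.0028).

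**Figure D3:**
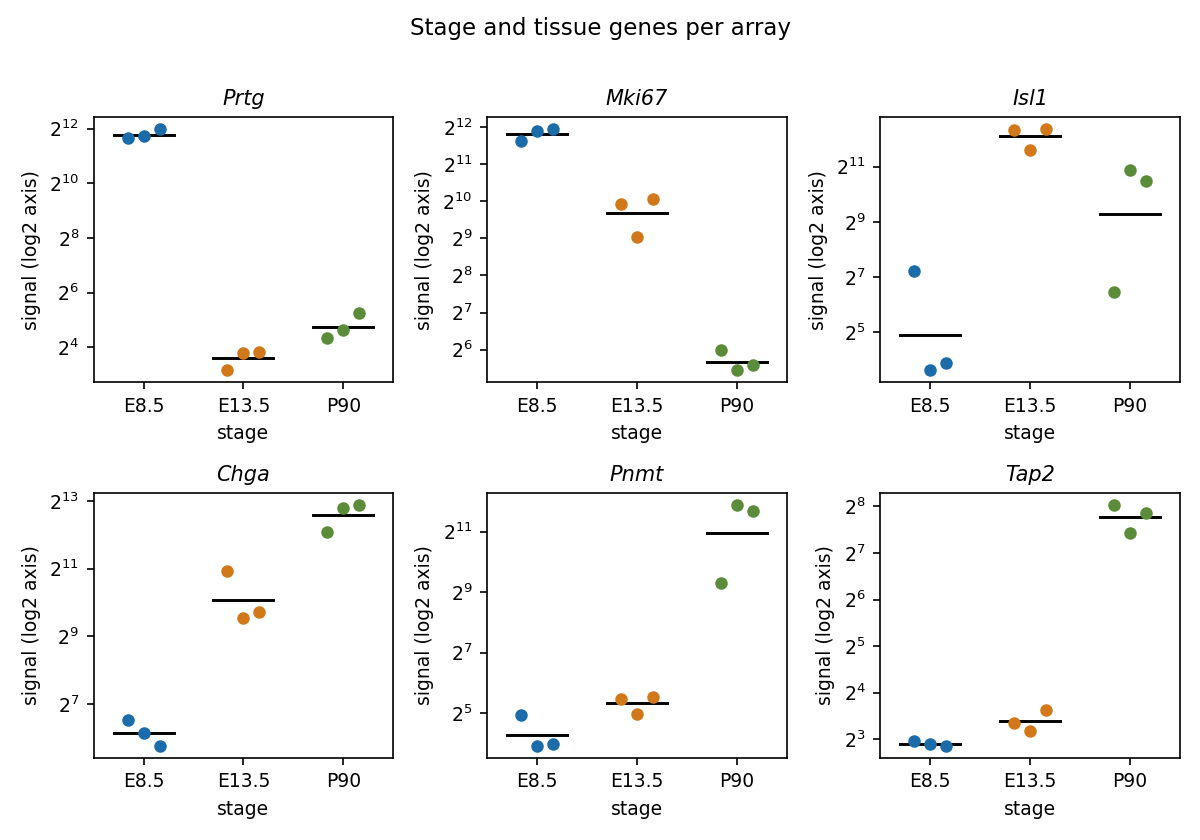
Signal of 6 genes named in the text (Prtg, Mki67, Isl1, Chga, Pnmt and Tap2) on the 9 arrays, on a log2 axis. Dots are arrays and black bars geometric means of stages. Mki67 steps down over the stages, Pnmt and Tap2 lie higher on the 3 P90 arrays than on any other array, and the P90 arrays are spread from 88.9 to 1876 for Isl1.

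Over all genes, 1303 of 13747 passed the test, 487 higher and 816 lower at P90, and 1269 changed at least 2-fold. In 2882 of the 12947 genes with no empty value, the stages did not overlap, 22.3% against 10% by chance. Called genes numbered 682 without E13.5 replicate 3 and 834 in a fit of only these 6 arrays, and 492 were higher and 1310 lower without E13.5 replicate 2.

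The last comparison set the P90 adrenal medulla against E8.5 neural crest. Chgb, a granule protein, went from 36.2 ± 23.8 to 7481 ± 941 (n = 3 each; log2 7.26 ± 0.55, adjusted p = 6.27e-06), and Chga rose as well (log2 6.15 ± 0.44, adjusted p = 4.92e-06). Crabp2, which carries retinoic acid to the nucleus, fell from 3900.1 ± 622 to 5.56 ± 1.09 (n = 3 each; log2 -7.49 ± 0.49, adjusted p = 3.66e-06). Of 143 repair genes, 3 rose, 51 fell and 89 were not called (over the list alone, 4 rose and 55 fell). The median repair gene was -0.68, against 0.005 for all genes, and camera ranked them below other genes only at its preset correlation (camera adjusted p = 4.51e-09 and 0.183 with estimated correlation; fry adjusted p = 0.000968).

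The 6 repair genes with the largest fall were Rad54l, to 17.8 ± 2.05 (n = 3; log2 -4.49 ± 0.32, adjusted p = 4.82e-06), Exo1, to 35.3 ± 5.93 (n = 3; log2 -4.28 ± 0.29, adjusted p = 4.2e-06), Cenps (log2 -4.22 ± 0.36, adjusted p = 1.27e-05), Tipin (log2 -3.84 ± 0.5, adjusted p = 0.000249), Ube2t (log2 -3.81 ± 0.23, adjusted p = 3.09e-06) and Brca1, with 1 empty value at E8.5 (log2 -3.76 ± 0.34, adjusted p = 3.72e-05). The 3 that rose were Rrm2b, a p53-inducible subunit of ribonucleotide reductase, from 111 ± 30.8 to 621 ± 168 (n = 3 each; log2 2.33 ± 0.47, adjusted p = 0.00401), the glycosylase Neil1 (log2 1.17 ± 0.26, adjusted p = 0.00778) and Paxx (log2 0.85 ± 0.24, adjusted p = 0.0257). Paxx lost its call without E8.5 replicate 2 or 3 or P90 replicate 2 or 3 (adjusted p from 0.0523 to 0.122), and also with the mean of all probe sets (log2 change 0.54, adjusted p = 0.0814, range 1.92e-06 to 0.122). Parp1 (log2 -2.2 ± 0.41, adjusted p = 0.00257), Msh6 (log2 -3.28 ± 0.56, adjusted p = 0.00155) and Xrcc1 (log2 -1.57 ± 0.38, adjusted p = 0.0118) fell too. Without the array of each stage with the largest Actb difference, Xrcc1 (adjusted p = 0.0772, range 3.62e-06 to 0.0772) and Paxx (adjusted p = 0.0855) were not called.

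In homologous recombination, 12 fell and 12 were not called (over the list alone, 13 fell) out of 24 (camera adjusted p = 1.29e-06 and 0.063 with estimated correlation), and in damage signalling 11 fell and 8 were not called (over the list alone, 12 fell) out of 19. For damage signalling, camera gave adjusted p = 2.33e-07 and 0.129 with estimated correlation. In the Fanconi anaemia list, 7 fell and 11 were not called (over the list alone, 7 fell) out of 18. For Fanconi anaemia, camera gave adjusted p = 0.000641 and 0.129 with estimated correlation. In base excision, 1 rose, 8 fell and 10 were not called (over the list alone, 2 rose and 9 fell) out of 19, where Lig1 (-3.63) and Apex1 (-2.04), named after their values were seen, fell with Parp1. For base excision, camera gave adjusted p = 0.00364 and 0.221 with estimated correlation. In mismatch repair, 3 fell and 4 were not called (over the list alone, 3 fell) out of 7, with Exo1, Msh6 and, named after its value was seen, Pms2 (-1.6) as the fallers. For mismatch repair, camera gave adjusted p = 0.0305 and 0.141 with estimated correlation. In nucleotide excision, 6 fell and 20 were not called (over the list alone, 6 fell) out of 26. For nucleotide excision, camera gave adjusted p = 0.0351 and 0.498 with estimated correlation. In translesion synthesis, 2 fell and 12 were not called (over the list alone, 2 fell) out of 14, the fallers being Pcna (-2.86) and Rad18 (-2.08), named after their values were seen (camera adjusted p = 0.155). In end joining, 1 rose, 1 fell and 8 were not called (over the list alone, 1 rose and 1 fell) out of 10, with Paxx up and Xrcc5 (-1.47; named after its value was seen) down. For end joining, camera gave adjusted p = 0.642. In direct reversal and the nucleotide pool, 1 rose, 1 fell and 4 were not called (over the list alone, 1 rose and 2 fell) out of 6, Rrm2b being the riser and Dut (-2.64; named after its value was seen) the faller. For direct reversal, camera gave adjusted p = 0.808. Dut lost its call without any E8.5 array or P90 replicate 2 or 3 (adjusted p from 0.0526 to 0.0761), Pcna without E8.5 replicate 2 or P90 replicate 3 (adjusted p from 0.051 to 0.0517) and Xrcc5 without E8.5 replicate 2 or 3 (adjusted p from 0.0504 to 0.0539).

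Most cell cycle and growth genes fell together with these. For mitosis, 31 fell and 3 were not called (over the list alone, 32 fell) out of 34, such as Top2a, the topoisomerase of cycling cells (log2 -5.85 ± 0.46, adjusted p = 7.91e-06), and Mki67 (log2 -5.76 ± 0.38, adjusted p = 3.66e-06). For mitosis, camera gave adjusted p = 1.09e-25 and 0.063 with estimated correlation. In DNA replication, 30 fell and 5 were not called (over the list alone, 32 fell) out of 35, such as the helicase subunit Mcm5 (log2 -5.81 ± 0.45, adjusted p = 6.51e-06). For DNA replication, camera gave adjusted p = 6.34e-19 and 0.063 with estimated correlation. In the embryonic growth programme, 9 fell and 2 were not called (over the list alone, 9 fell) out of 11, led by Igf2bp1 (log2 -6.78 ± 0.41, adjusted p = 3.09e-06) and Sox2 (log2 -5.97 ± 0.49, adjusted p = 9.87e-06). For growth genes, camera gave adjusted p = 8.14e-09 and 0.0851 with estimated correlation. Of 12 cell cycle inhibitors, 3 rose, 1 fell and 8 were not called (over the list alone, 3 rose and 1 fell), Btg2 (log2 2.52 ± 0.33, adjusted p = 0.000246) among the risers (camera adjusted p = 0.0869). Of 16 p53 targets, 4 rose, 1 fell and 11 were not called (over the list alone, 4 rose and 1 fell), with Trp53inp1 (log2 2.68 ± 0.52, adjusted p = 0.00347) and Btg2 rising (camera adjusted p = 0.22).

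Some crest and neural tube genes were lower than at E8.5. For crest specification, 12 fell and 9 were not called (over the list alone, 13 fell) out of 21, led by Zic1 (log2 -6.54 ± 0.42, adjusted p = 3.66e-06) and including Foxd3 (log2 -2.78 ± 0.46, adjusted p = 0.00129). For crest genes, camera gave adjusted p = 5.77e-06 and 0.0749 with estimated correlation. Of 15 neural tube progenitor genes, 6 fell and 9 were not called (over the list alone, 7 fell), such as Wnt1 (log2 -4.63 ± 0.25, adjusted p = 2.39e-06). For neural tube genes, camera gave adjusted p = 5.69e-05 and 0.0909 with estimated correlation. Of 16 chromaffin and catecholamine genes, 10 rose and 6 were not called (over the list alone, 11 rose), such as Pnmt (log2 5.81 ± 0.56, adjusted p = 3.21e-05) and Dbh (log2 4.32 ± 0.61, adjusted p = 0.000439). For catecholamine genes, camera gave adjusted p = 7.91e-05 and 0.11 with estimated correlation. Of 17 secretory granule and neuropeptide genes, 9 rose and 8 were not called (over the list alone, 11 rose). For granule genes, camera gave adjusted p = 6.99e-07 and 0.11 with estimated correlation. On P90 replicate 1 the granule list lay lower than on replicates 2 and 3 by a median of -1.18 and the catecholamine list by -1.73. Of 22 pan-neuronal genes, 6 rose and 16 were not called (over the list alone, 7 rose), such as the vesicle protein Rab3c (log2 5.28 ± 0.65, adjusted p = 0.000173). For pan-neuronal genes, camera gave adjusted p = 0.00053 and 0.289 with estimated correlation. Of 18 sensory neuron genes, 2 rose, 1 fell and 15 were not called (over the list alone, 2 rose and 1 fell; camera adjusted p = 0.372). Their risers were Th (log2 5.07 ± 0.44, adjusted p = 2.63e-05; 1 empty value at P90) and Isl1 (log2 3.64 ± 0.99, adjusted p = 0.0196; stages overlapped), which lost its call without E8.5 replicate 2 or 3 or P90 replicate 2 or 3 (adjusted p from 0.0747 to 0.0846), and the faller was Neurog2 (-4.56), named after its value was seen. In glia, 3 rose, 1 fell and 9 were not called (over the list alone, 5 rose and 1 fell) out of 13, with the lipid carrier Apoe (log2 4.79 ± 1.15, adjusted p = 0.0109) rising most. For glia, camera gave adjusted p = 0.0928.

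Other cell type markers at P90 against E8.5 included 17 macrophage genes, of which 12 rose and 5 were not called (over the list alone, 14 rose), such as H2-Eb1 (log2 5.08 ± 0.36, adjusted p = 4.81e-06). For macrophages, camera gave adjusted p = 3.72e-07 and 0.063 with estimated correlation. In class I antigen presentation, 12 rose and 2 were not called (over the list alone, 13 rose) out of 14, such as B2m, the light chain of class I molecules (log2 3.39 ± 0.59, adjusted p = 0.00166), and Tap2 (log2 3.32 ± 0.22, adjusted p = 4.01e-06). For class I presentation, camera gave adjusted p = 2.06e-09 and 0.0293 with estimated correlation, which kept the call. Of 7 adrenal cortex genes, 3 rose and 4 were not called (over the list alone, 3 rose), with a median of 0.65; Fdx1 rose most (log2 5.25 ± 0.61, adjusted p = 0.000111). In endothelium, 5 rose and 12 were not called (over the list alone, 6 rose) out of 17, such as Vwf, a clotting factor of vessel walls (log2 2.9 ± 0.41, adjusted p = 0.000452). For endothelium, camera gave adjusted p = 0.000894 and 0.305 with estimated correlation. In epithelium, 7 fell and 6 were not called (over the list alone, 7 fell) out of 13, such as Krt8 (log2 -3.85 ± 0.41, adjusted p = 6.44e-05). For epithelium, camera gave adjusted p = 0.00234 and 0.183 with estimated correlation. In mesenchyme, 3 rose, 5 fell and 10 were not called (over the list alone, 3 rose and 6 fell) out of 18, Fn1 (log2 -3.84 ± 0.63, adjusted p = 0.00121) falling most; the median was 0.03 and the mean -0.07, with a test that pointed down. For mesenchyme, camera gave adjusted p = 0.658. In red cells, 1 rose, 3 fell and 6 were not called (over the list alone, 1 rose and 6 fell) out of 10, with the embryonic globin Hbb-bh1 (log2 -5.61 ± 0.77, adjusted p = 0.000364) and Hbb-y (log2 -6.9 ± 0.52, adjusted p = 1.06e-05) falling. For red cells, camera gave adjusted p = 0.0928. Of 12 muscle and somite genes, 2 fell and 10 were not called (over the list alone, 2 fell), namely Myf5 (log2 -3.23 ± 0.56, adjusted p = 0.0017) and Tcf15 (log2 -2.37 ± 0.51, adjusted p = 0.00605); the median was 0.08 (-0.04 with quantile normalization), the mean -0.5, and the test pointed down. For muscle, camera gave adjusted p = 0.688. Among genes with no empty value, the rest with the largest rise, passing over a Riken gene, were Mmd2 (log2 6.12 ± 0.51, adjusted p = 1.06e-05) and the calcium channel subunit Cacna2d1 (log2 6.02 ± 0.46, adjusted p = 6.46e-06), and Prtg (log2 -6.36 ± 0.29, adjusted p = 8.28e-07) fell too, the last of the 5 largest falls. Without probe sets ending in _x_at and _s_at, Mmd2 (log2 change 2.1, adjusted p = 0.0677, range 3.01e-12 to 0.0677) and Hbb-y (log2 change -3.34, adjusted p = 0.051, range 1.05e-11 to 0.051) were not called.

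Over all genes, 3209 of 13747 passed the test, 1497 higher and 1712 lower at P90, and 3068 changed at least 2-fold. In 5688 of the 13184 genes with no empty value, the stages did not overlap, 43.1% against 10% by chance. Called genes numbered 2057 without E8.5 replicate 2. The balance turned without P90 replicate 3 (1287 higher and 1128 lower) and with planned array weights (4708 higher and 4542 lower).

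Against E8.5, 40 repair genes were lower at E13.5 and 51 at P90, and 38 were lower at both. Independent lists of those sizes among 143 genes would share 14.3. The changes at the later stages correlated over repair genes at r = 0.93, across genes that are not independent replicates, against a mean r of 0.50 over all genes in 100 simulated draws of unchanged groups. Their covariance was 1.26, against 0.0795 for unchanged groups. Draws of unchanged groups gave 0 repair genes lower at both stages. Few calls arise without any change, so that count cannot weigh shared controls. The 3 E8.5 arrays cannot be split into parts of at least 2, so shared controls may add to the excess. The values argue against them as its whole source. The count of 38 was 25 without either E8.5 replicate 2 or 3. Repair genes' median log2 signal per array was 8.25 to 8.28 at E8.5, 7.25 to 7.43 at E13.5 and 7.11 to 7.28 at P90. A test over all 3 stages called 3619 of 13747 genes, of which 13 were called in no pair of stages. Of called genes under the rule for naming or named after their values were seen, 60 of 86, 44 of 56 and 75 of 83 in the 3 comparisons stayed past the threshold without each of the 9 arrays.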

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

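Alternatives using the Actb difference, only genes without an empty cell or gene-by-gene array weights were chosen after seeing the data. Without 1 array in turn, called genes ranged from 1355 to 2832 (E13.5 against E8.5), 682 to 1802 (P90 against E13.5) and 2057 to 3928 (P90 against E8.5), and in the test of any stage from 2413 to 4487. Called repair genes ranged from 27 to 48, 1 to 12 and 41 to 62, those lower at both later stages from 25 to 43, and the repair set's adjusted p from 1.12e-09 to 1.03e-08, 0.171 to 0.333 and 2.09e-09 to 6.05e-08. Counts stayed within 1.5 times of those reported in 21 of 27, 21 of 27 and 22 of 27 alternatives for all genes. For repair genes this held in 22 of 27, 10 of 27 and 25 of 27, for repair genes lower at both stages in 22 of 27, and for any stage in 22 of 25.

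At P90 against E13.5, the 5 repair genes became 9 with quantile normalization (1 higher and 8 lower, 11.1% higher against 0%), 2 with a pseudocount of 64, 3 with only the arrays compared, 3 with the mean of all probe sets and 3 with a replicate block. With only the arrays compared, 834 genes were called. Replicate numbers did not pair the samples: deviations of same-numbered arrays correlated at -0.37 to 0.39, and beyond those 3 repair genes the block moved no count by over 1.5 times. Planned array weights, whose estimate did not converge and whose weights ran from 0.147 to 16.9, gave 8163, 10022 and 9250 genes, 88, 93 and 98 repair genes, 11213 genes for any stage and 64 repair genes lower at both stages. The gene-by-gene weights, from 0.185 to 4.97, gave 6803, 6222 and 8072 genes, 76, 54 and 90 repair genes, 9852 for any stage and 58 at both. With an estimated correlation the repair set was not called at E13.5 (adjusted p = 0.175, range over alternatives 2.57e-10 to 0.175) or at P90 against E8.5 (adjusted p = 0.183, range 7.57e-11 to 0.183).

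With the Actb difference as a covariate, P90 against E13.5 gave 2039 genes and 9 repair genes. Without the array of each stage with the largest Actb difference (E8.5 replicate 1, E13.5 replicate 2 and P90 replicate 2), there were 27 repair genes at E13.5 against E8.5, 8 at P90 against E13.5 and 25 at both, and 2089 genes at P90 against E8.5. That setting moved the share of higher calls from 56.2% to 67.3% and from 37.4% to 21.3% at E13.5 against E8.5 and P90 against E13.5. Quantile normalization with the Actb covariate gave 3916, 2574 and 5248 genes, 19 repair genes at P90 against E13.5 (21.1% of them higher) and 5941 genes for any stage.

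The median change of all genes moved by over 0.1 at E13.5 against E8.5, from 0.02 to 0.13 with planned array weights and to 0.12 without the 3 arrays with the largest Actb difference. At P90 against E13.5 it moved from -0.05 to -0.18 with either array weights, -0.21 without those 3 arrays, -0.20 without E13.5 replicate 2, -0.16 without P90 replicate 1 and 0.06 without P90 replicate 3. Among named genes, 2282 of 2496 values at E13.5 against E8.5 kept direction and call, with 188 weaker, 10 stronger and 15 moved. At P90 against E13.5, 1636 of 1768 did (89 weaker, 19 stronger, 24 moved), and at P90 against E8.5, 2268 of 2319 (35 weaker, 16 stronger). The 1 reversed value was H2-Ab1 at E13.5 against E8.5, at -0.50 without probe sets ending in _x_at and _s_at. Fewer arrays enter some of these settings; otherwise the cause was not tested.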

Other observations

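The 8 tests of the first 3 patterns weighed here (repair genes, empty cells and P90 replicate 1) were chosen only after the result was seen, as were, for the last, a minimum of 3 genes per list and the treatment of empty values, and the counts over other splits of the arrays were planned. Hox genes, which set position along the body axis, numbered 20; 5 fell and 15 were not called (adjusted over the list alone, 5 fell) at E13.5 against E8.5 (camera adjusted p = 0.0359 and 0.473 with estimated correlation), 3 fell and 17 were not called (over the list alone, 3 fell) at P90 against E13.5 (camera adjusted p = 0.755), and 1 rose, 6 fell and 13 were not called (over the list alone, 1 rose and 7 fell) at P90 against E8.5 (camera adjusted p = 0.0464 and 0.419 with estimated correlation). Hoxa2 fell at E13.5 (log2 -2.59 ± 0.4, adjusted p = 0.00117) and Hoxd3 at P90 against E8.5 (log2 -3.52 ± 0.29, adjusted p = 1.06e-05), while Hoxd8 (2.45), named after its value was seen, rose. Of 14 imprinted growth genes, 1 rose, 1 fell and 12 were not called (over the list alone, 1 rose and 1 fell) at E13.5 against E8.5 (camera adjusted p = 0.65), 1 rose, 3 fell and 10 were not called (over the list alone, 1 rose and 3 fell) at P90 against E13.5 (camera adjusted p = 0.261), and 1 rose, 4 fell and 9 were not called (over the list alone, 2 rose and 4 fell) at P90 against E8.5 (camera adjusted p = 0.515); the last median of -0.09 turned to 0.06 with quantile normalization. Plagl1 fell at P90 against E13.5 (log2 -3.31 ± 0.58, adjusted p = 0.00373) and Mest against E8.5 (log2 -3.1 ± 0.52, adjusted p = 0.00143), and Dlk1 (3.20), named after its value was seen, rose against E8.5. Of 24 immediate early genes, 4 rose, 2 fell and 18 were not called (over the list alone, 4 rose and 3 fell) at E13.5 against E8.5 (camera adjusted p = 0.332), 6 rose and 18 were not called (over the list alone, 7 rose) at P90 against E13.5 (camera adjusted p = 5.31e-05 and 0.357 with estimated correlation), and 8 rose, 1 fell and 15 were not called (over the list alone, 12 rose and 1 fell) at P90 against E8.5 (camera adjusted p = 5.13e-05 and 0.183 with estimated correlation). Egr1 rose at E13.5 (log2 2.69 ± 0.57, adjusted p = 0.00736) and at P90 against E8.5 (log2 4.99 ± 0.57, adjusted p = 0.0001).

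Of 18 glycolysis genes, 3 rose, 6 fell and 9 were not called (over the list alone, 4 rose and 9 fell) at E13.5 against E8.5 (camera adjusted p = 0.0458 and 0.672 with estimated correlation), 1 rose, 1 fell and 16 were not called (over the list alone, 1 rose and 1 fell) at P90 against E13.5 (camera adjusted p = 0.268), and 1 rose, 8 fell and 9 were not called (over the list alone, 2 rose and 11 fell) at P90 against E8.5 (camera adjusted p = 0.00742 and 0.476 with estimated correlation). Slc2a1, a glucose transporter, fell at E13.5 (log2 -2.99 ± 0.43, adjusted p = 0.000792), and Hk2 rose at P90 against E13.5 (log2 3.05 ± 0.58, adjusted p = 0.00585). Of 32 oxidative phosphorylation genes, limma called 0 (0 higher and 0 lower at unadjusted p under 0.05; 0 over the list alone) at E13.5 against E8.5 (camera adjusted p = 0.967), limma called 0 (0 higher and 2 lower at unadjusted p under 0.05; 0 over the list alone) at P90 against E13.5 (camera adjusted p = 0.261), and limma called 0 (0 higher and 2 lower at unadjusted p under 0.05; 0 over the list alone) at P90 against E8.5 (camera adjusted p = 0.248); the medians of -0.02 and -0.37 against E8.5 turned to 0.15 and 0.01 with quantile normalization. Of 23 antioxidant genes, 1 fell and 22 were not called (0 over the list alone, where limma gave 0 higher and 1 lower at unadjusted p under 0.05) at E13.5 against E8.5 (camera adjusted p = 0.938), 2 rose and 21 were not called (over the list alone, 3 rose) at P90 against E13.5 (camera adjusted p = 0.0151 and 0.823 with estimated correlation), and 4 rose, 1 fell and 18 were not called (over the list alone, 4 rose and 1 fell) at P90 against E8.5 (camera adjusted p = 0.0801); the first median of -0.12 turned to 0.16 with quantile normalization. The faller at E13.5, Gsta4, lost its call without E8.5 replicate 2 or 3 or E13.5 replicate 2 or 3 (adjusted p from 0.0617 to 0.143), while Gpx3 rose at P90 against E13.5 (log2 2.09 ± 0.33, adjusted p = 0.0022). Of 19 cholesterol synthesis genes, limma called 0 (0 higher and 1 lower at unadjusted p under 0.05; 0 over the list alone) at E13.5 against E8.5 (camera adjusted p = 0.434), 2 rose and 17 were not called (over the list alone, 2 rose) at P90 against E13.5 (camera adjusted p = 0.388), and 2 rose and 17 were not called (over the list alone, 2 rose) at P90 against E8.5 (camera adjusted p = 0.903). Their medians of -0.1 and -0.16 against E8.5 turned to 0.05 and 0.09 with quantile normalization, and at P90 against E13.5 the median was -0.04 (0.14 with quantile normalization), the mean 0.13 and the test up. Dhcr7 rose (log2 2.42 ± 0.49, adjusted p = 0.00861), and Ebp lost its call without any 1 of the 9 arrays (adjusted p from 0.0578 to 0.13). Of 23 ribosomal protein genes, limma called 0 (0 higher and 3 lower at unadjusted p under 0.05; 0 over the list alone) at E13.5 against E8.5 (camera adjusted p = 0.00397 and 0.639 with estimated correlation), limma called 0 (0 higher and 2 lower at unadjusted p under 0.05; 0 over the list alone) at P90 against E13.5 (camera adjusted p = 0.035 and 0.823 with estimated correlation), and 5 fell and 18 were not called (over the list alone, 5 fell) at P90 against E8.5 (camera adjusted p = 2.75e-05 and 0.387 with estimated correlation); Rps25 fell at P90 against E8.5 (log2 -1.85 ± 0.42, adjusted p = 0.00842). With quantile normalization, 4 rose and 11 fell in glycolysis at E13.5, 5 rose among antioxidant genes at P90 against E13.5, and at P90 against E8.5 3 rose and 11 fell in glycolysis, 2 rose and 2 fell in oxidative phosphorylation, 10 rose and 2 fell among antioxidant genes, 13 rose and 1 fell among immediate early genes and 9 fell among ribosomal proteins. Of 3 sex chromosome transcripts, 1 fell and 2 were not called (over the list alone, 1 fell) at E13.5 against E8.5, limma called 0 (0 higher and 0 lower at unadjusted p under 0.05; 0 over the list alone) at P90 against E13.5, where the median was -0.54 and the mean 0.27, and 2 fell and 1 were not called (over the list alone, 2 fell) at P90 against E8.5. The faller at E13.5, Kdm5d, lost its call without E8.5 replicate 1 or 2 or E13.5 replicate 3 (adjusted p from 0.0592 to 0.0867). Xist had a signal of 73.8 on E8.5 replicate 1 and 39.8 on E13.5 replicate 1, against 1428 to 6129 on the other arrays. The sources used here do not give the samples' sex, so a difference in sex between replicates is left open, also for Kdm5d.

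Repair genes were lower at E13.5 than at E8.5 by a median of -0.52. With quantile normalization the median was -0.534, which argues against scaling as the whole source. With the Actb difference as a covariate it was -0.474, but mean Actb differences were alike at both stages, so this cannot exclude RNA integrity. The Gapdh difference averaged 1.71 ± 0.22 at E8.5 and 2.94 ± 1.75 at E13.5 (SD, n = 3), and was not used as a covariate. The 4 repair lists with the lowest medians, homologous recombination, Fanconi anaemia, mismatch repair and damage signalling (0 rose and 30 fell of 68, median -0.97), lay lower than the others (1 rose and 10 fell of 75, median -0.32) by a difference of -0.645, but they were grouped after their medians were seen, so this supports no explanation. The other repair genes lay at percentile 0.18 of 10000 matched random lists. But 8 also serve DNA replication, and random lists ignore correlation between genes. For both groups, fewer dividing cells, RNA integrity and an untested difference between the tissues cannot be told apart.

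Empty cells fell on whole stages: 65, 244 and 118 probe sets were empty on all 3 arrays of E8.5, E13.5 and P90. That makes 427, against 1.04 by chance, which argues against cells lost without regard to stage. Other probe sets of the same gene ranked among the highest 3 of the 9 arrays in 1911 of 3535 pairs of an empty cell and such a probe set, 54.1% (51.8 to 56.4, 95% bootstrap interval over 1430 genes) against 33.3% by chance, so high values may have been left out of the table. Among annotated genes, 10 of 26 sensory neuron and 10 of 29 pan-neuronal genes had a probe set empty on all 3 arrays at E13.5, and 7 of 14 adrenal cortex and 4 of 19 chromaffin genes at P90. Counts for these lists may therefore be too low; no biological explanation was tested.

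On P90 replicate 1, catecholamine genes lay below P90 replicates 2 and 3 by a median of -1.73 over 13 genes (bootstrap interval over genes -2.27 to 0.20), against 0.25 for all genes. The Actb difference was 1.36 there against 4.09 and 3.51, and 4 of 5 lists of metabolism and ribosomal proteins also lay outside the central 95% of 10000 matched random lists (oxidative phosphorylation 1.31 and antioxidant 1.48, percentile 100 each; cholesterol synthesis -0.46, percentile 0; glycolysis 0.01, percentile 0.13), so the signal or RNA integrity of the whole array cannot be told apart from a difference in its cells. A larger share of other adrenal cells could account for the pattern, as endothelium (1.06, percentile 99.97) and mesenchyme (0.89, percentile 99.87) were higher, but the adrenal cortex list, at 1.19 over 4 genes, reached percentile 95.7, short of the bound set for it, and cannot be told apart from chance on these 4 genes. Fdx1, 1 of the 4, had signals of 8173, 4787 and 4152 on replicates 1, 2 and 3. Differences between the animals were not tested.

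Splits of 6 arrays into 3 against 3 number 10 and can never give a share under 0.05. At E13.5 against E8.5 the real split gave 2267 genes and 41 repair genes (highest other 0 and 0, 1 of 10 each). Its repair set adjusted p was 2.06e-09 (others 0.000142 to 0.0774). At P90 against E8.5 it gave 3209 and 54 (highest other 0 and 0, 1 of 10 each), with 4.51e-09 (others 3.5e-05 to 0.0451). So at its preset correlation camera also passed the repair set under most wrong splits, which called 0 genes. At P90 against E13.5 it gave 1303 genes (highest other 1040; 1 of 10), 5 repair genes (highest other 11; 2 of 10) and 0.190 (smallest other 0.197). The split with 1040 and 11 genes set E13.5 replicates 1 and 3 and P90 replicate 1 apart. It parts mean signals (295 to 327 against 173 to 223) and Actb differences (0.85 to 2.87 against 3.51 to 7.0), not Gapdh's. RNA integrity and brightness are candidate sources. With the Actb covariate the real split gave 2039 genes. Of the 280 splits of the 9 arrays, 100 were drawn, the real one among them. Only it reached 3619 genes for any stage (highest other 1661) and 38 repair genes lower at both stages (highest other 33). The shares of 1 in 100 argue against chance without excluding it.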
